A study of Mus musculus with 10 samples.

How the data were processed

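The measurement was RNA-seq of the midbrain of mouse embryos at embryonic day 14.5. Total RNA was extracted with the Direct-zol RNA Miniprep Kit, per the labels' protocols. The authors deposited 1 table of gene counts for the series, whole numbers per Entrez gene ID with no normalization. Reads were aligned with HISAT2 and counted with featureCounts on the mm39 build, per the submitters' processing notes. Their versions, the gene annotation, the strandedness of the library and the treatment of reads that map to several places are not given in the sources used here. All of these bear on the counts: without strand, overlapping and antisense genes cannot be told apart, and genes with near-identical copies lose or share reads.

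The columns of the table were matched to samples by their labels, and 0 columns stayed without a sample. The table held 30935 gene IDs, of which 30648 had a symbol in the RefSeq gene table for GRCm38.p6; the 287 others held 0.0116% of the counts. That table was of another build than the counts, so it served only for names and for which genes lie near Rbfox1, and no coordinates are given. Transcript length and GC content came from the longest GENCODE M21 transcript (GRCm38) of each gene, found for 14119 of the 15288 genes tested (92.4%). Libraries of the same group were compared for duplicates: the lowest chi-square per degree of freedom of any pair was 6.17 over 12695 genes, far above sampling noise, so all 10 were kept. The precision of a value is set by the spread between 5 libraries per group and by the 16246892 to 20255728 counts behind each. The samples are described as independent, but litters, dissection days and library batches are not given in the sources used here.

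Counts were tested with edgeR 4.0.16 in R 4.3.3: low genes were removed with filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood fit with group as the only term gave a two-sided F test per gene. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F, and 95% intervals used the test's degrees of freedom. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. Fold changes are deletion against wild-type. Rbfox1, Rbfox2 and Rbfox3 were also compared by an exact permutation test over all 252 assignments of the libraries. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for the 36 of 37 lists with 3 or more tested members. The list of mitochondrially encoded genes was not analysed here, since none of its 15 members matched an ID. Lists, tests and alternatives were fixed before the data were examined, except where the text says otherwise.

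The genes named were chosen by a rule: Rbfox1, Rbfox2, Rbfox3 and their listed neighbours; the 12 largest rises and 12 largest falls past the threshold with a mean of at least 1 CPM and a proper symbol, filled up to 6 by the smallest p where a direction had fewer; the 4 members with the smallest p of each called list; and the leading member of another list where it passed adjusted over the list alone. A result that this rule gave is left out where its gene is not reported here.

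The alternatives tried were size factors of DESeq2's kind (RLE) and upper-quartile factors, no filter and a filter of at least 1 CPM in at least 5 libraries, the replicate number as a block, the Y-linked level as a covariate, 1 surrogate variable (sva 3.50.0), leaving out each library, DESeq2 1.42.0, limma-voom, an estimated correlation in camera, fry, and windows of 5 Mb and all of chromosome 16. Removing each library's trend on transcript length, with or without GC content, was added after the data were seen; the trend was a spline with 4 degrees of freedom per variable, fitted to genes with a mean log2 CPM above 3 and used as an offset.

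The gene test was tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes among 15288. For deletion against wild-type, it recovered 34% of genes changed 1.25-fold, 84% of those changed 1.5-fold and 98% of those changed 2-fold, and 7.06% of its calls were false. The changed genes were drawn only from those above a floor of mean CPM. Recovery of lower genes, such as Ciita at a mean of 2.45 CPM, was not measured. With a simulated length slope between the groups, 18.6% of calls were false, and 5.99% after the trend was removed. Every deletion library was given the same slope and the wild-type libraries none. In the data the slopes also varied within the groups (SD 0.022 in the wild-type and 0.057 in the deletion group). The simulation thus does not show how many calls are false in these data once the trend is removed. In a simulation of 36 lists with the axon guidance list raised by 0.2 on the log2 scale, camera called 1 list, that one. The genes were simulated independently of each other, so this does not show how often camera calls lists whose genes vary together. In the data, the estimated correlation between genes was 0.59 for the ribosomal protein list.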

Results

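Gene counts from RNA-seq were analysed for the midbrain of mouse embryos at embryonic day 14.5. The embryos were wild-type or homozygous for a deletion of HAR.321, a stretch of the Rbfox1 locus. Human accelerated regions (HARs) are sequences that are conserved among vertebrates and changed fast on the human lineage. Rbfox1 encodes an RNA-binding protein that controls alternative splicing in neurons. Each group held 5 libraries, described as independent biological samples: wild-type 1, 2, 4, 5 and 6, and deletion 2, 3, 4, 5 and 6. The total per library ran from 16246892 to 20255728 counts, and 18365 to 19452 genes had a count. The files gave no gene positions, and exon use was not analysed here, so every value below is a level of the whole gene.

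The first comparison asked whether the level of Rbfox1 differed without the element. Rbfox1 (Entrez gene 268859) stood at 149 ± 11.0 CPM in the wild-type group and 161 ± 13.7 CPM in the deletion group (SD, n = 5 each), a log2 fold change of 0.11 (SE 0.07, 95% interval -0.03 to 0.26) that did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.607). 4 of the 5 deletion libraries lay above the wild-type mean, and the raw Rbfox1 counts ran from 2514 in deletion 2 to 3449 in deletion 6. Its relatives, which bind the same RNA motif, also differed by less than the spread between libraries: Rbfox2 had a log2 fold change of 0.04 (SE 0.06, adjusted p = 0.888; -0.07 with the trend on transcript length and GC content removed) and Rbfox3, the NeuN antigen of mature neurons, one of 0.06 (SE 0.08, adjusted p = 0.872). An exact two-sided permutation test of the mean log2 CPM gave p = 0.151 for Rbfox1, 0.270 for Rbfox2 and 0.484 for Rbfox3, with adjusted values of 0.405, 0.405 and 0.484 over these 3 genes. The smallest p that 5 against 5 allows is 0.00794. Leaving out wild-type 2, whose Rbfox1 level was the highest of its group, gave p = 0.0397 for Rbfox1 in the exact permutation test. HAR.321 was not placed on the counted exons here, so the Rbfox1 level was not used as a check of the labels.

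**Figure D1:**
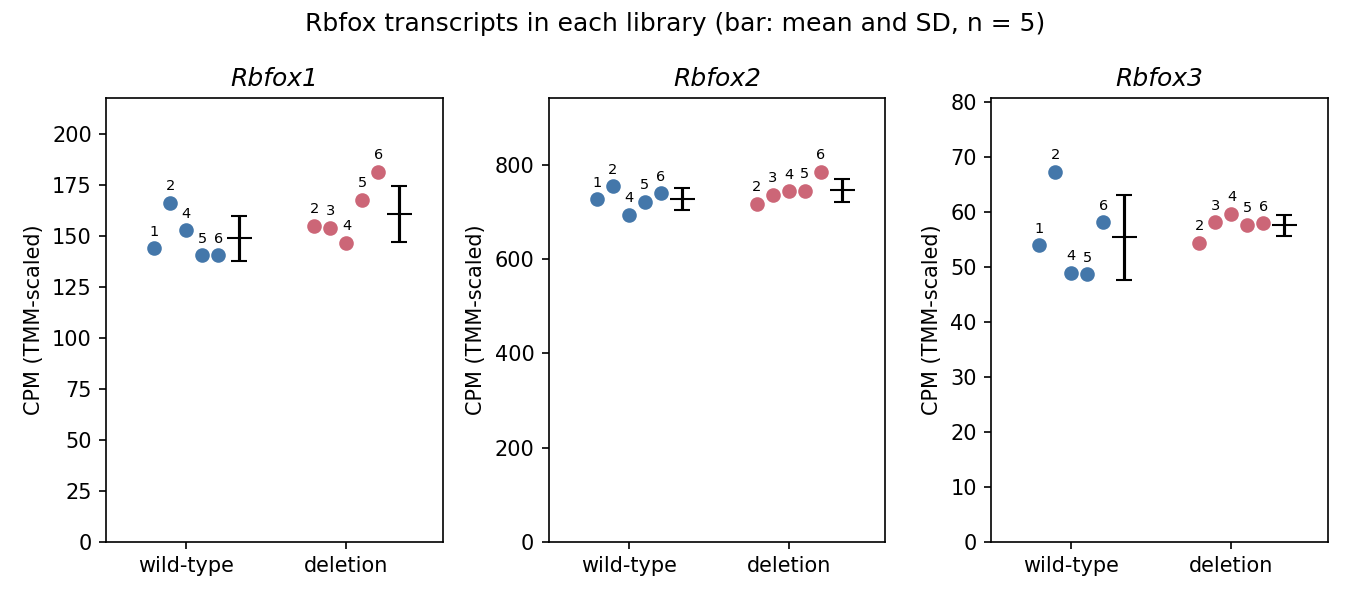
TMM-scaled CPM of Rbfox1, Rbfox2 and Rbfox3 on the vertical axes, one point per library with its replicate number, for the 5 wild-type (blue) and 5 deletion (red) libraries; the bar beside each group is its mean and SD. The groups overlap for all 3 genes, and the Rbfox1 means are 149 and 161 CPM.

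The genes around Rbfox1 on chromosome 16 were compared next, since a regulatory element can act on neighbours. Of 21 neighbours listed before the data were examined, 18 were tested, and none passed edgeR's test, over all genes or adjusted over the list alone (8 were higher and 10 lower; 1 had an unadjusted p under 0.05; none passed DESeq2 or limma-voom). Tmem186, which encodes a mitochondrial membrane protein, was the neighbour with the smallest p, at 35.7 ± 2.69 CPM in the wild-type and 30.5 ± 2.50 CPM in the deletion group (log2 fold change -0.23, SE 0.09, adjusted p = 0.306), and all 5 deletion libraries lay below the wild-type mean. Pmm2, an enzyme of protein glycosylation, had a log2 fold change of -0.13 (SE 0.08), and Ciita, the activator of MHC class II genes, one of -0.44 (SE 0.26) at a mean of only 2.45 CPM. Abat, which breaks down GABA, Grin2a, an NMDA receptor subunit, and the deubiquitinase gene Usp7 had log2 fold changes of -0.01 (SE 0.06), 0.06 (SE 0.16) and 0.02 (SE 0.05). The other listed neighbours lay between -0.17 for Nagpa (SE 0.20) and 0.20 for Tekt5 (SE 0.21). Within 10 Mb of Rbfox1, 0 of 112 tested genes passed edgeR's test against 9 of 15136 elsewhere (Fisher's exact test, two-sided, p = 1). With only 0.0595% called elsewhere, 0 was the likely count in the window, so this test could hardly show a local effect. At an unadjusted p under 0.01, the counts were 1 of 112 and 559 of 15136 (Fisher's exact test, two-sided, p = 0.197). In that window, 10 of 112 genes had an unadjusted p under 0.05 in edgeR, against 1611 of 15288 over all genes. DESeq2 called 1 of 65 there, against 261 of 8080 over all genes, and limma-voom called 0. The window thus held no excess of such genes. The 1 gene was the phosphatidylinositol 4-kinase gene Pi4ka (log2 fold change 0.26 in edgeR, SE 0.06, adjusted p = 0.102), which is named after its value was seen.

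The comparison over all genes asked what else differed in the midbrain. Of 15288 genes tested, 9 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, and all 9 were lower in the deletion group. Frat2, a gene of the Wnt pathway whose product binds GSK3, fell furthest, from 23.7 ± 2.26 to 15.2 ± 2.05 CPM (SD, n = 5; log2 fold change -0.64, SE 0.11, adjusted p = 0.0296). Dbi, which encodes an acyl-CoA-binding protein, fell by 0.47 on the log2 scale (SE 0.09, adjusted p = 0.0474), and Hypk, a partner of the N-terminal acetyltransferase NatA, by 0.43 (SE 0.08, adjusted p = 0.0373). Rpl36 and Rpl21, proteins of the large ribosomal subunit, fell by 0.44 and 0.37 (SE 0.07 and 0.06, adjusted p = 0.0296 for both). Cox7c and Ndufc2, subunits of respiratory complexes IV and I, fell by 0.36 each (SE 0.07 for both, adjusted p = 0.0373), and the spliceosome gene Zmat2 by 0.35 (SE 0.06, adjusted p = 0.0373). The remaining gene, Gm1673, fell by 0.45 (SE 0.07, adjusted p = 0.0296) and is named after its value was seen. For each of the 9, all 5 deletion libraries lay below every wild-type library. The 9 were chosen by a test on these same values, so this adds no support. Of the tested genes, 380 (2.49%) had groups that did not overlap, where chance gives 0.794%. Genes are not independent of each other, and this excess was not tested.

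No gene passed as higher in the deletion group in edgeR, where 859 higher and 752 lower genes had an unadjusted p under 0.05. DESeq2 called 134 genes higher and 127 lower, and limma-voom 1 higher and 8 lower. The higher genes with the smallest p did not pass (adjusted p from 0.0565 to 0.0621). They were Prrc2c, an RNA-binding protein (log2 fold change 0.32, SE 0.06), Srgap1, a GTPase-activating protein downstream of Slit and Robo (0.31, SE 0.06), Dync1h1, the heavy chain of cytoplasmic dynein (0.41, SE 0.08), Polr2a, the largest subunit of RNA polymerase II (0.36, SE 0.07), and the neuron navigator genes Nav2 and Nav1 (0.42, SE 0.09, and 0.37, SE 0.08). Scaling by the upper quartile called 15 genes, 3 of them higher. The count of 9 rested on single libraries: it was 357 without deletion 4 (137 higher and 220 lower), 88 without wild-type 2 (57 higher and 31 lower), 1 without wild-type 4, 3 without deletion 3 (all among the 9), 3 without deletion 6 (0 of them among the 9), and 0 without any other library.

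Among 36 gene lists fixed before the data were examined and tested with camera at a preset correlation of 0.01, 3 were lower and 4 higher in the deletion group. Of the cytosolic ribosomal protein genes, 62 of 64 were lower, with a median log2 fold change of -0.19 (camera adjusted p = 4.67e-33; adjusted p = 0.420 with an estimated correlation). In edgeR, 2 passed over all genes and 38 adjusted over the list alone. DESeq2 called 22 over all genes and limma-voom 2. Rpl11 (-0.30, SE 0.06) and Rps23 (-0.29, SE 0.06) followed Rpl36 and Rpl21, with adjusted p = 0.0582 and 0.0757 over all genes. The nuclear genes of oxidative phosphorylation were lower in 34 of 34 cases, with a median of -0.21 (camera adjusted p = 1.74e-23; adjusted p = 0.313 with an estimated correlation). In edgeR, Cox7c alone of the list passed over all genes (Ndufc2 is not on it) and 21 adjusted over the list alone. DESeq2 called 8 over all genes and limma-voom 1. Examples that passed in edgeR only over the list were Ndufa1 (-0.49, SE 0.10), Cox5b (-0.33, SE 0.07) and Uqcrq (-0.37, SE 0.09). DESeq2 called Cox5b and Uqcrq over all genes as well. Markers of neural progenitors were lower in 19 of 28 cases, with a median of -0.10 (camera adjusted p = 0.0290; adjusted p = 0.669 with an estimated correlation). Only Id1, a target of BMP signalling, passed adjusted over that list alone (log2 fold change -0.47, SE 0.13, lower in 5 of 5 deletion libraries). Hes6 (-0.25, SE 0.09) and the Wnt receptor gene Fzd10 (-0.27, SE 0.12) were among the lower members and Notch2 (0.39, SE 0.12) among the higher ones, and none of them passed in edgeR. Ribosomal protein genes have many processed pseudogenes of nearly the same sequence, so their counts are uncertain where reads could be placed on either.

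Genes associated with autism were higher in 30 of 34 cases in the deletion group, with a median log2 fold change of 0.15 (camera adjusted p = 2.27e-09; adjusted p = 0.420 with an estimated correlation). None passed over all genes in edgeR (16 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0), and 14 passed adjusted over the list alone. Those with the smallest p were Tsc2 (0.30, SE 0.07) and Tsc1 (0.21, SE 0.06), which together restrain mTOR, Reln (0.34, SE 0.09), the secreted guide of migrating neurons, and Auts2 (0.25, SE 0.07). For each of them, all 5 deletion libraries lay above the wild-type mean, though the groups overlapped for Reln. Synaptic and excitability genes were higher in 41 of 50 cases, with a median of 0.08 (camera adjusted p = 4.15e-07; adjusted p = 0.562 with an estimated correlation). Syn1 (0.27, SE 0.08), of synaptic vesicles, Pclo (0.30, SE 0.09), of the active zone, and the adhesion gene Nlgn3 (0.22, SE 0.07) were among its leading members and did not pass in edgeR. Axon guidance genes were higher in 27 of 32 cases, with a median of 0.13 (camera adjusted p = 0.000108; adjusted p = 0.393 with an estimated correlation). Its leading members were the semaphorin receptor genes Plxna1 (0.26, SE 0.07) and Plxnd1 (0.32, SE 0.11) and the Slit receptor genes Robo2 (0.20, SE 0.07) and Robo1 (0.21, SE 0.07), and none passed in edgeR over all genes or over the list. DESeq2 called Plxna1 over all genes. Red blood cell genes were higher in 8 of 8 cases, with a median of 0.18 (camera adjusted p = 0.0290; adjusted p = 0.546 with an estimated correlation). Alas2, of haem synthesis, passed adjusted over that list alone (0.47, SE 0.16), while the globin genes Hba-a2 (0.25, SE 0.12), Hba-a1 (0.15, SE 0.11) and Hbb-bs (0.13, SE 0.10) did not. The alpha-globin copies are near-identical, so their counts are uncertain. With an estimated correlation, 0 of the 36 lists passed camera (4 had an unadjusted p under 0.05), and 0 passed fry (6 had an unadjusted p under 0.05). The call of the red blood cell list ended without deletion 4 (adjusted p = 0.336), deletion 5 (0.0537), wild-type 1 (0.150), wild-type 2 (0.0502), wild-type 4 (0.0529) or wild-type 5 (0.120). That of the progenitor list ended without deletion 3 (0.0697), deletion 6 (0.361), wild-type 1 (0.0542), wild-type 5 (0.0879) or wild-type 6 (0.0607).

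**Figure D2:**
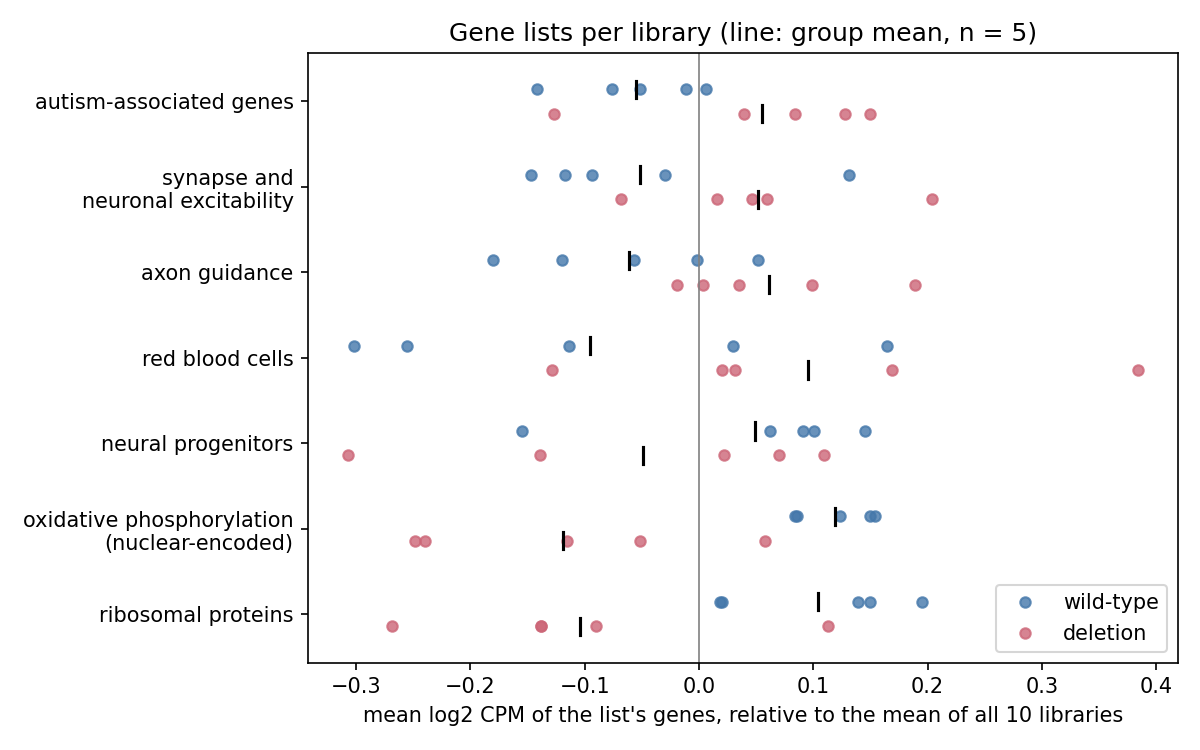
Each point is 1 library, placed on the horizontal axis by the mean log2 CPM of a list's tested genes relative to the mean of all 10 libraries, for the 7 lists that camera called; blue is wild-type, red is deletion, and the short lines are group means (n = 5). For ribosomal proteins deletion 4 (0.11) lies among the wild-type libraries, apart from the other deletion libraries.

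Transcript length moved with most of these lists. The median of the longest annotated transcript was 783 bases for oxidative phosphorylation genes, against 8509 bases for autism-associated and 6129 bases for axon guidance genes; red blood cell genes, which were higher, are short (701 bases). Across 10618 genes, which are not independent replicates, the log2 fold change correlated with log2 transcript length (Pearson r = 0.472, Spearman rho = 0.460). Genes with a transcript under 1 kb had a median log2 fold change of -0.17, and those over 8 kb one of 0.09. The slope of each library's log2 CPM on log2 length was -0.035 ± 0.022 per doubling in the wild-type and 0.035 ± 0.057 in the deletion group (SD, n = 5; exact permutation test, two-sided, p = 0.0397, adjusted p = 0.198 over 10 library measures). Deletion 4 had a slope of -0.055, within the range of the wild-type libraries. With the trend on length and GC content removed, 23 genes passed, of which 6 were among the 9 (Frat2, Rpl36, Rpl21, Hypk, Zmat2 and Gm1673); Cox7c (-0.07, SE 0.07, adjusted p = 0.790), Ndufc2 (-0.17, SE 0.06, adjusted p = 0.359) and Dbi (-0.30, SE 0.08, adjusted p = 0.136) did not pass. With the trend on length alone removed, 0 passed (1190 had an unadjusted p under 0.05), and the smallest adjusted p among the 9 was 0.134. In that fit the log2 fold changes were -0.59 for Frat2 (SE 0.11), -0.45 for Hypk (SE 0.08), -0.31 for Zmat2 (SE 0.06), -0.30 for Rpl21 (SE 0.06), -0.28 for Dbi (SE 0.09), -0.27 for Gm1673 (SE 0.06), -0.26 for Rpl36 (SE 0.06) and -0.17 for Cox7c and Ndufc2 (SE 0.07 for both).

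**Figure D3:**
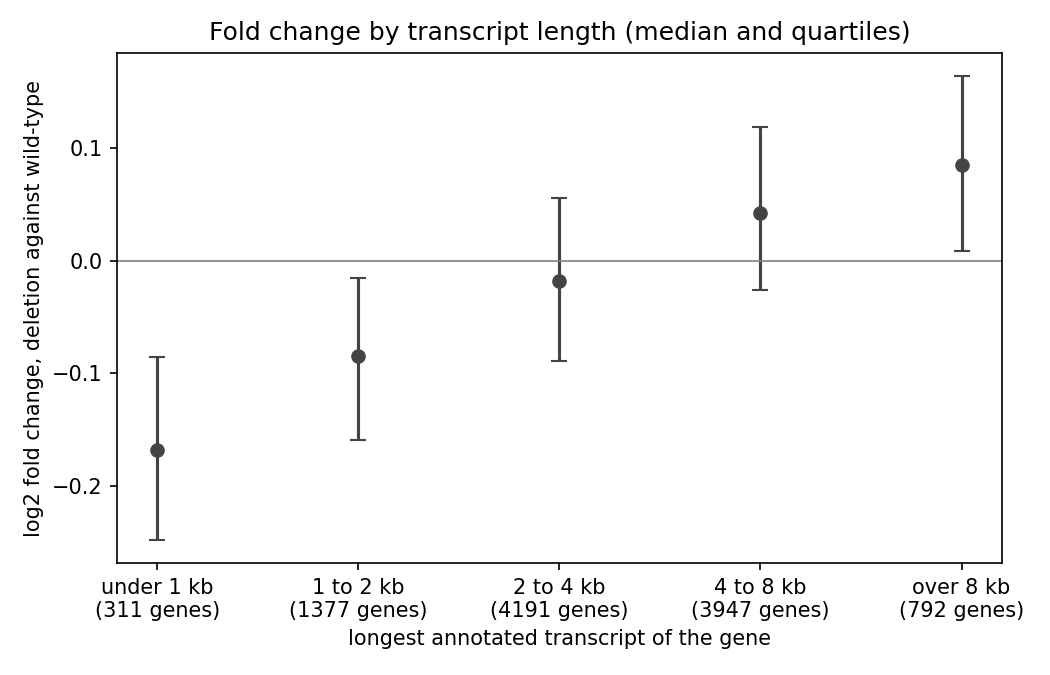
Median log2 fold change of deletion against wild-type (points) with quartiles (bars) for genes grouped by the length of their longest annotated transcript; the number of genes stands under each group. The median goes from -0.17 under 1 kb to 0.09 over 8 kb.

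The other 29 lists did not pass camera (adjusted p from 0.126 to 0.947). The cell types of the midbrain were among them. Dopaminergic neuron markers had a median log2 fold change of 0.08 (20 genes, adjusted p = 0.439), GABAergic ones 0.09 (16 genes, adjusted p = 0.126), glutamatergic ones -0.01 (19 genes, adjusted p = 0.885) and serotonergic ones 0.09 (8 genes, adjusted p = 0.609). Markers of new and maturing neurons had a median of 0.04 (30 genes, adjusted p = 0.126). In that list 4 higher members and 1 lower one passed adjusted over the list alone, led by Map1b, a microtubule-binding protein of growing axons (0.40, SE 0.09, above the wild-type mean in 5 of 5 deletion libraries). None passed over all genes in edgeR or limma-voom, while DESeq2 called 3 members (Stmn1, Map1b and Ncam1). Cell cycle genes had a median of -0.07 (36 genes, adjusted p = 0.210), which rested on single libraries: the list was called lower without wild-type 2 (median -0.21, adjusted p = 5.9e-06) and without deletion 2 (-0.14, adjusted p = 0.0123), and its median was 0.04 without deletion 6 (adjusted p = 0.595). These values used the preset correlation of 0.01, while the one estimated for this list over all libraries was 0.70. With that estimate camera gave an adjusted p of 0.836 over all libraries, so the smaller p-values carry little weight. GABAergic markers were called higher without deletion 3 (adjusted p = 0.0444), and new and maturing neurons without deletion 4 (adjusted p = 0.0492). Both also passed with the trend on length alone removed (adjusted p = 0.0487 and 0.0315), but not with an estimated correlation in that fit (adjusted p = 0.360 and 0.514). Of 9 alternatives other than leaving out a library, camera called GABAergic markers in 2 (lowest adjusted p = 0.0274) and new and maturing neurons in 3. Splicing regulators other than the Rbfox family had a median of -0.02 (30 genes, adjusted p = 0.447). With the trend on length alone removed, camera gave this list an adjusted p of 0.0468, and 0.519 with an estimated correlation. None of its members passed over all genes in edgeR (2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0). Of cell types around the neural tissue, microglial markers had a median of 0.05 (18 genes, adjusted p = 0.609), endothelial ones -0.07 (18 genes, adjusted p = 0.562) and meningeal ones -0.08 (17 genes, adjusted p = 0.947). Single members passed adjusted over their own list alone. They were the lysosomal gene Laptm5 among microglial markers (0.67, SE 0.14, from 8.69 ± 1.76 to 13.8 ± 1.01 CPM), the fibronectin gene Fn1 among meningeal ones (0.42, SE 0.10), Foxj1, a master gene of motile cilia, among choroid plexus ones (-0.38, SE 0.12) and H1f0, a linker histone gene that is not tied to DNA replication, among replication-dependent histones (-0.26, SE 0.07). None of these 4 passed over all genes in edgeR, while DESeq2 called Fn1 and H1f0.

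The libraries were much alike, with correlations of log2 CPM between 0.976 and 0.988, and did not separate by group. The leading principal component held 28.7% of the variance among the 500 most variable genes. It followed sex-linked genes: 2 wild-type and 3 deletion libraries had 3979 or more counts of Y-linked genes and at most 159 of Xist, and the others had at most 26 Y-linked counts and 27701 or more of Xist. The groups differed by less than the spread between libraries on this component (exact permutation test, two-sided, p = 0.690) and in total counts (18338775 ± 1221434 against 18472288 ± 1515610, SD, n = 5; exact permutation test, p = 0.905).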

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

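The tests of pseudogene reads and of the caudal edge of the dissection were chosen after the values were seen. In each group, a library was marked when it stood far from the other 4 by Dixon's gap test. This was done for 214 sets of 5 values and marked 10, about the 1 in 20 that chance gives, so single marks carry little weight.

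Deletion 4 was marked for 3 measures of the whole library. Its 10 most abundant genes held 5.04% of the counts, against 4.13% to 4.36% in the other deletion libraries. Its mean correlation with the other libraries was 0.979, against 0.983 to 0.984. Its log2 CPM rose by 0.25 per 10 points of GC content, against slopes of -0.08 to -0.03. The same library was marked for fibronectin (Fn1, 47.6 CPM against 35.7 to 37.6) and for alpha-globin (Hba-a1, 1170.3 CPM against 858 to 914). Without it, 357 genes passed in place of 9.

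Other marks stood alone. Cox7c reached 67.3 CPM in deletion 3, against 58.2 to 60.5 in the other deletion libraries and a wild-type mean of 78.5. Abat was at 123 CPM in wild-type 5, against 111 to 113, and Auts2 at 151 CPM in wild-type 4, against 177 to 181. The neural progenitor list had a mean log2 deviation of -0.15 in wild-type 2, against 0.06 to 0.14, and the microglial list one of -0.21 in wild-type 1, against 0.00 to 0.08.

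The pattern most in need of a second look is that the ribosomal protein and oxidative phosphorylation lists, of short transcripts, were lower in the deletion group and the autism, synaptic and axon guidance lists, of long transcripts, higher, while the red blood cell list, short as well, was higher (median 0.18). A bias between libraries in how transcripts of different length or GC content are represented is a candidate explanation, and each list was set against 20 other genes per member matched on length, GC content and abundance. The matched genes came from outside the lists, but unlisted genes of the same families, such as Ndufc2, could be among them. How close the matches were was not measured. For autism-associated and synaptic genes the difference between groups shrank from 0.11 and 0.10 to 0.024 and 0.044 (SE 0.045 and 0.047). Such a bias would give this shrinkage. The exact permutation test, however, did not pass before matching either (p = 0.103 and 0.167, against 0.619 and 0.373 after it). Its result after matching thus does not show that matching removed a difference. Camera at its preset correlation still called both with the length and GC trend removed (adjusted p = 0.0116 and 0.0119). With an estimated correlation it called neither (adjusted p = 0.312 and 0.703). For both lists, the bias and a change with the deletion cannot be told apart as sources of the difference between groups. For axon guidance it shrank from 0.12 to 0.066 (exact permutation p = 0.238), and for ribosomal proteins and oxidative phosphorylation from -0.21 and -0.24 to -0.091 and -0.107 (exact permutation p = 0.0476 for both, adjusted p = 0.286 over 36 lists), and camera at the preset correlation still called these 3 with the trend removed (adjusted p = 0.0298, 2.96e-11 and 0.00067; adjusted p = 0.312, 0.360 and 0.360 with an estimated correlation); for them the bias and a change of the lists with the deletion cannot be told apart, since a part remained that was smaller than the move of the matched genes or, for axon guidance, within the spread of the libraries. The size of the libraries did not follow their length slope (Pearson r = -0.214, permutation p = 0.551; Spearman rho = -0.188, p = 0.608; r = -0.176 without wild-type 2 and deletion 2, over 10 libraries), while reads shared with processed pseudogenes stay open: 218 genes under 1000 bases outside both families had a median of -0.16 (bootstrap interval -0.18 to -0.14), but they make up most of the shortest genes, whose fall was already known.

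Of 100 of the 126 splits of the 10 libraries into groups of 5, the real one included, 2 gave 9 or more genes; the highest other split gave 12, and that split exchanged wild-type 2 with deletion 4. Few of these splits thus reached the real count of genes, but this does not exclude chance. The split that gave 12 had a higher absolute correlation of log2 fold change with log2 transcript length (0.516) than the real one (0.471). Of the 100 splits, the real one included, 3 reached 0.471 or more, and the median of the other splits was 0.199. The highest correlation, 0.533, came from a split that called 0 genes. The count of the real groups fell to 0 or 1 without wild-type 1, 4, 5 or 6 or deletion 2 or 5, to 3 without deletion 3 (all among the 9) and 3 without deletion 6 (0 among the 9), and rose to 88 without wild-type 2 and 357 without deletion 4. Chance is not excluded for the count of lists either. Of the 100 splits, 43 gave 7 or more, the median of the other splits was 6, and the highest gave 13.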

How the results depend on the processing

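Removing the length trend, with or without GC content, was chosen after seeing the data. The count of 9 changed genes was 15 with upper-quartile factors (3 higher), 69 with no filter (26 higher), 65 with 1 surrogate variable (24 higher), 23 with the length and GC trend removed (10 higher), 0 with the length trend removed and 261 with DESeq2 (134 higher), which holds 8 of the 9. It ranged from 0 to 357 when libraries were left out in turn. RLE factors, the stricter filter and limma-voom each gave 9, and the Y-linked covariate 13. The cause of these differences was not tested, except that no filter tested more genes (22889) and DESeq2 fewer (8080). The 7 changed lists were 12 with the length trend removed, 0 with an estimated correlation and 0 with fry, and 5 to 8 with a library left out; the red blood cell list did not pass with no filter (adjusted p = 0.141). Rbfox1 kept a positive log2 fold change, 0.07 to 0.15, and passed under none of 21 alternatives; its permutation p ranged from 0.0397 (without wild-type 2) to 0.302 (without deletion 6). Within 10 Mb of Rbfox1, 1 gene had an unadjusted p under 0.01. With the replicate number as a block, 0 genes passed (924 had an unadjusted p under 0.05) and 8 lists did, of which 6 were among the 7. The neural progenitors did not pass with the block (adjusted p = 0.214), while cartilage and bone was among the lists gained (adjusted p = 0.0122). The 4 shared numbers gave no sign of pairing the libraries. Same-numbered deviations correlated by -0.187, -0.238, 0.044 and 0.006, against -0.204 to 0.190 for other pairs. While 0 libraries correlated best with their own number, a weak shared effect could be missed this way. Over the 65 genes that the naming rule chose, 1349 values were computed under alternatives: 1171 stayed on their side of the threshold, 81 lost significance, 97 gained it and 0 called values changed sign, while 35 uncalled ones did. Of the 167 values of genes called in edgeR, 86 still passed. Depth limits genes of a few CPM, such as Ciita, more than those named as changed.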

Other observations

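The test of serotonergic against hindbrain genes was chosen after the values were seen, and so were the genes named here. Some markers of neighbouring tissues had no counts. Hoxb2 of the hindbrain, Myog of muscle and Krt5 of skin had 0 counts in all 10 libraries together, which at this depth is not proof of absence. Other members of their lists had enough counts to be tested: 5 hindbrain, 8 skeletal muscle and 4 skin genes. The 3 genes without counts thus do not show that these tissues were absent. Dopaminergic neurons were present in every library, with 300 to 466 counts of Th and 159 to 320 of Slc6a3.

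Serotonergic genes varied more between libraries than between groups. Tph2, the enzyme of brain serotonin synthesis, ran from 55 counts in wild-type 1 to 300 in wild-type 6, and the serotonin transporter gene Slc6a4 from 127 to 495 in the same libraries. A different position of the caudal edge of the dissection is a candidate explanation, since serotonergic neurons arise in the rostral hindbrain, next to the midbrain. Taken as deviations from the group mean, the serotonergic and hindbrain lists had a Pearson r of 0.556 over 10 libraries (permutation p = 0.0950, adjusted p = 0.285 over 3 relations) and a Spearman rho of 0.709 (p = 0.0272), with r = 0.882 without wild-type 6 and wild-type 1. The direction is the one a shifted edge would give, but Pearson's test did not pass, so chance stays open over 10 libraries. The hindbrain list also moved with the forebrain and diencephalon list, and both lists name Gbx2. Relative to the mean of all libraries, they stood at 0.85 and 0.48 in deletion 2, and -0.50 and -0.40 in deletion 6. Their signs were opposite in wild-type 4 (-0.18 and 0.08) and wild-type 6 (-0.03 and 0.04). This relation was not tested. A shifted caudal edge would not by itself move forebrain genes, so these values do not single it out. The serotonergic and dopaminergic lists had r = 0.352 (p = 0.320; rho = 0.188, p = 0.608; r = -0.084 without the same libraries). No biological explanation was tested for it.

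The 7SL RNA genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, had log2 fold changes of -1.02 (SE 0.21) and -1.03 (SE 0.21) in the deletion group, with adjusted p = 0.0688 and 0.0601 in edgeR, and were below the wild-type mean in 5 of 5 deletion libraries. They are near-identical copies and count as 1 measurement of uncertain placing. The red blood cell list is made of short transcripts yet was higher in the deletion group, and against matched genes its difference was 0.31 in place of 0.19 (exact permutation p = 0.0397, adjusted p = 0.286 over 36 lists).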
